A study of Mus musculus with 9 samples.

How the data were processed

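RNA from lymphatic endothelial cells, sorted as CD45-negative, CD31-positive and podoplanin-positive cells from meninges, diaphragm and skin of untreated male C57BL/6 mice, was extracted with the Arcturus PicoPure kit and amplified with the NuGEN Ovation RNA-Seq System V2, per the labels' protocols. The values used are the deposited read counts per Ensembl gene, 1 column per library, which per the submitters' processing notes were made with FastQC, STAR and HTSeq on the mouse build mm9. Tool versions, the annotation, the strand setting and the handling of reads with several matches are not given in the sources used here. Counts of near-identical copies, and of overlapping or antisense genes, are therefore uncertain. No coordinates are given, because the mouse annotation at hand is of another build.

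The table held 23018 genes and all 9 libraries, and every column was used. A symbol was present for 15853 genes. A further 7078 were named by their Ensembl identifier from the reference annotation, 87 were left unnamed, and 22 symbols that a spreadsheet had turned into dates were replaced in the same way. Total counts ran from 26075366 (Diaphragm replicate 1) to 34592850 (Meninges replicate 3). Counts of replicates differed far beyond sampling noise (chi-square per degree of freedom between 308.3 and 506.9), so no library was counted as a repeat of another. The 4 Y-linked genes examined had counts in each library, and Xist was not analysed here.

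Genes were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr, which left 14831, libraries were scaled by TMM, and a quasi-likelihood model (glmQLFit, glmQLFTest) with 1 mean per tissue was fitted to the 9 libraries together. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with their standard errors. Where 1 tissue had no count, a bound was computed against a floor of 3 counts over the group. The biological coefficient of variation was 1.243, so single genes needed large differences to pass. Floors cover counting error only.

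The design, the alternatives, the gene lists and the naming rule were fixed before the data were examined. The rule names 6 LEC and gate genes always. For each meningeal comparison it takes the 8 highest and 8 lowest called genes by log2 fold change with an average log2 CPM of at least 3, no overlap between libraries and no predicted-gene or clone name. For diaphragm against skin it takes 5 and 5, and for the comparison with both tissues 8 and 8. From each gene list it takes up to 4 called members with the smallest adjusted p and, where fewer than 2 were called, also the 2 members with the highest average level. Not every gene the rule takes is printed. Gene lists, 37 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and adjusted over all lists and comparisons. Of the 42 list calls, 6 held with an estimated correlation.

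Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors, upper-quartile factors, no filter, a filter of 50 counts in 3 libraries, fits with 2 tissues, the replicate number as a block, limma voom with quality weights, glmTreat at a log2 fold change of 1, removal of genes of other cell types, a robust fit and each library left out in turn. The removal of genes of other cell types also took out ribosomal protein and mitochondrially encoded genes. After seeing the data, a fit with 1 meningeal library and a fit with the fibroblast marker level as a covariate were added. The tests were run on simulated counts with 50 genes changed per fold size. For meninges against diaphragm, edgeR recovered 0 genes at 2-fold, 1 at 4-fold, 9 at 8-fold and 19 at 32-fold, and called 2 unchanged genes, while DESeq2 called 191 unchanged genes. For meninges against skin, edgeR recovered 0, 3, 9 and 21 and called 3 unchanged genes, and DESeq2 called 167. limma voom recovered 0, 2, 8 and 10 genes against diaphragm and 0, 2, 9 and 8 against skin, and called 5 unchanged genes in each. The counts were drawn with the gene dispersions that edgeR had estimated, so the 3 tests were not set on equal terms. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.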

Results

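RNA was sequenced from lymphatic endothelial cells (LECs) sorted by flow cytometry from the meninges, the diaphragm and the skin of untreated wild-type male C57BL/6 mice aged 10 weeks. The gate took cells without the leukocyte antigen CD45 that carried both CD31 (encoded by Pecam1) and podoplanin (Pdpn). Each tissue gave 3 libraries, 9 in all, and the comparisons ask how LECs of the membranes around the brain differ from LECs of 2 peripheral tissues. Total counts per library ran from 26075366 to 34592850. Nothing in the labels says whether the 3 libraries of a tissue came from separate animals or pools, so the p-values measure only the spread between these libraries. Between 13241 genes (Skin replicate 3) and 17245 genes (Meninges replicate 2) had at least 1 count. The 2 mitochondrial ribosomal RNAs took 17.3% ± 6.1 of counts in the meningeal libraries, 23.8% ± 5.0 in the diaphragm libraries and 29.4% ± 2.1 in the skin libraries (SD, n = 3 each).

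Transcripts of the lymphatic master regulator Prox1 were abundant in all 9 libraries, at a normalised level of 1087 ± 326 CPM (counts scaled to the library's effective size) in meninges, 1810 ± 188 in diaphragm and 1930 ± 123 in skin (SD, n = 3 each). Flt4, the receptor for the lymphatic growth factor VEGF-C, stood at 2386 ± 995, 2473 ± 478 and 3442 ± 303 CPM in the same order. Pdpn was at 142 ± 47, 160 ± 76 and 160 ± 38 CPM, and Pecam1 at 425 ± 181, 771 ± 161 and 801 ± 157 CPM. Lyve1, a hyaluronan receptor of initial lymphatics, measured 1605 ± 898 CPM in meninges, 3715 ± 1064 in diaphragm and 4957 ± 155 in skin. Of these 5 genes, Lyve1 differed between meninges and skin (log2 fold change -1.63, standard error 0.34, edgeR adjusted p = 0.0326), and no other difference among them passed the test in any of the 3 comparisons. The Lyve1 call held in 5 of the 9 fits that left out 1 library and was lost without Meninges replicate 2 or 3 or Skin replicate 1 or 3. Ptprc, which encodes CD45, was at 2.1 ± 1.8 CPM in meninges and 0.71 ± 1.15 in skin, while the 3 diaphragm libraries ranged from 0.0369 to 118.5 CPM. All 4 Y-linked genes examined had counts in every library.

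The first principal component, with 23.4% of the variance, placed the 3 meningeal libraries between -178.75 and -106.32, the diaphragm libraries between -4.13 and 25.96 and the skin libraries between 42.18 and 198.21. Within meninges and within skin, the order on this component also followed the number of genes with a count, which was 17245 in Meninges replicate 2 and 13241 in Skin replicate 3. Within diaphragm it did not. Tissue and the number of genes detected are thus not separated on the first component. The second component held 16.3% of the variance.

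**Figure D1:**
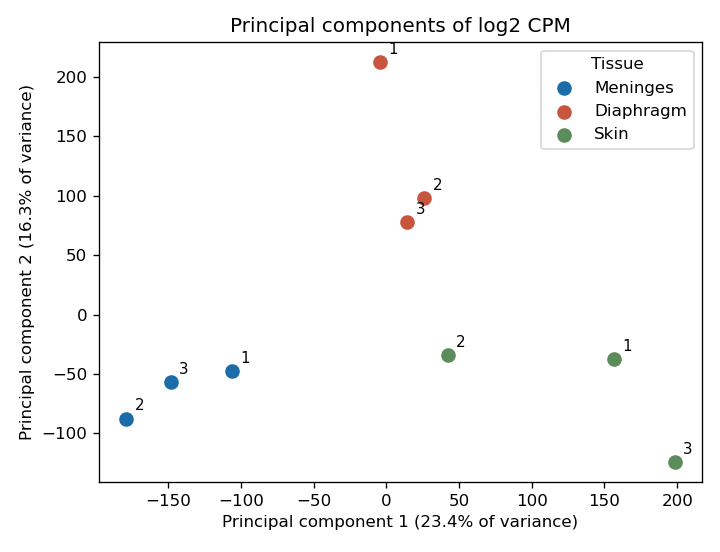
Principal components 1 (23.4% of variance) and 2 (16.3%) of log2 CPM over the genes tested, in arbitrary units, with 1 point per library, coloured by tissue and numbered by replicate. The 3 meningeal libraries lie between -178.75 and -106.32 on component 1, below every diaphragm and skin library.

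Compared with diaphragm, meningeal LECs carried less of a set of transcripts that were abundant in diaphragm LECs. Pkhd1l1, a large fibrocystin-like membrane protein, stood at 67.0 ± 43.1 CPM in meninges and 1217 ± 150 in diaphragm (log2 fold change -4.18, standard error 0.46, edgeR adjusted p = 0.00136). Wipf3, a regulator of the actin cytoskeleton (44.3 ± 15.2 against 472 ± 43 CPM), was lower as well. So were the extracellular matrix gene Tnxb (31.4 ± 12.8 against 464 ± 85) and Clca3a1, of the chloride channel accessory family (16.6 ± 16.8 against 469 ± 149). Also lower were Ackr3, a scavenging receptor of the chemokine CXCL12 (7.2 ± 5.5 against 157 ± 27 CPM), and both subunits of the nitric oxide receptor guanylate cyclase, Gucy1b3 (9.2 ± 3.4 against 157 ± 64) and Gucy1a3 (21.1 ± 15.4 against 166 ± 58). The Gucy1b3 call held in all 9 fits that left out 1 library, and the Gucy1a3 call in 3 of 9, being lost without any 1 diaphragm library, Meninges replicate 1 or 2, or Skin replicate 2. Among genes higher in meninges, Ttr, which encodes the thyroid hormone carrier transthyretin, reached 489 ± 53 CPM in meninges and had 3 counts over the diaphragm libraries together (edgeR adjusted p = 2.82e-05).

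Several other genes higher in meninges had few or no counts in diaphragm. Sfrp4, a secreted WNT antagonist, was at 99.4 ± 41.0 CPM in meninges and without a count in diaphragm, at least 11.41 higher on the log2 scale against a floor of 3 counts over the group. The bicarbonate transporter gene Slc4a10 (142 ± 75 CPM), the organic cation exporter gene Slc47a1 (62.0 ± 19.2) and Ndnf (61.1 ± 44.9) likewise had no count in diaphragm. Mmp13, a collagenase, differed between meningeal libraries, with 17.0, 947 and 335 CPM. The growth factor receptor Fgfr2 (254 ± 199 CPM against 0.0126 ± 0.0219), Emb (98.8 ± 17.7 against 0.0123 ± 0.0213) and Ctgf, a target of TGF-beta signalling (221 ± 55 against 28.7 ± 13.6), were also higher in meninges. In the other direction, genes with 1 count or none in meningeal libraries included Pax7, the transcription factor of muscle stem cells (0 against 182 ± 99 CPM), Muc16, a mucin of mesothelium (0 against 202 ± 295), and Chodl (0.0104 ± 0.0180 against 261 ± 137). Drp2, a dystrophin relative, was lower in meninges (4.67 ± 2.93 against 150 ± 11 CPM) and stood at 4.29 ± 4.19 CPM in skin.

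Of 25 LEC identity genes, 1 was called lower, Fgl2 (log2 fold change -2.18, standard error 0.32, edgeR adjusted p = 0.0097), and none higher, with 6 lower and 1 higher when adjusted over the list alone. The list was lower in meninges (camera adjusted p = 2.99e-04), but adjusted p = 0.471 with an estimated correlation, and its camera adjusted p was 0.0658 without Meninges replicate 2. Among 24 collecting vessel and valve genes, ephrin-B2 (Efnb2, 46.9 ± 12.3 against 308 ± 83 CPM) and the guidance cue Sema3a (86.0 ± 17.4 against 330 ± 40) were lower, the only called members. The Efnb2 call was lost without Meninges replicate 3, and the Sema3a call without any 1 meningeal or diaphragm library. With 2 higher and 3 lower when adjusted over the list alone, the list as a whole did not pass (limma camera adjusted p = 0.83). NOTCH pathway genes were lower as a list (camera adjusted p = 0.00966, adjusted p = 0.186 with an estimated correlation), with 1 called member of 17, the NOTCH regulator Dtx1 (22.7 ± 5.1 against 165 ± 48 CPM), also the only one when adjusted over the list alone. Without Diaphragm replicate 2 or Meninges replicate 2 the NOTCH list did not pass the limma camera test (adjusted p = 0.0666 and 0.081). It did not differ between meninges and skin (camera adjusted p = 0.937). In diaphragm it was higher than in skin (camera adjusted p = 0.0394, adjusted p = 0.275 with an estimated correlation). The difference is therefore not particular to meninges. Immediate early and dissociation-induced genes were lower as a list of 26 (camera adjusted p = 3.45e-14, adjusted p = 0.11 with an estimated correlation), with Jun called (45.0 ± 6.3 against 346 ± 151 CPM) and 11 members lower when adjusted over the list alone.

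Markers of other cell types differed between the tissues as well. Meningeal fibroblast markers were higher in meninges (camera adjusted p = 4.21e-13, adjusted p = 0.0423 with an estimated correlation). Of 11, Slc47a1 was called, and 8 passed when adjusted over the list alone. Bone and cartilage markers were higher too (camera adjusted p = 1.74e-08, adjusted p = 0.158 with an estimated correlation). The 2 called of 6, against 5 adjusted over the list alone, were Runx2, the osteoblast transcription factor (327 ± 242 against 0.319 ± 0.237 CPM), and Alpl, alkaline phosphatase (203 ± 87 against 2.53 ± 0.91). The bone and cartilage sum was 212.7 CPM in Meninges replicate 1, 1099 in replicate 2 and 850.4 in replicate 3, against 20.74 to 99.17 in diaphragm. With Meninges replicate 1 alone, its limma camera adjusted p was 0.185. The median log2 ratio of replicates 2 and 3 to replicate 1 was 2.73 over this list and 2.19 over the fibroblast list. Fibroblast markers were higher (camera adjusted p = 0.00186, adjusted p = 0.609 with an estimated correlation, camera adjusted p = 0.0807 without Meninges replicate 2), with no member called and 5 higher and 1 lower when adjusted over the list alone. Their summed level was 2321 CPM in Meninges replicate 1, 11450 in replicate 2 and 10710 in replicate 3, against 1593 to 2445 in diaphragm. Skeletal muscle markers, with Pax7 and Ttn (titin) called of 18 and 13 lower when adjusted over the list alone, were lower in meninges (camera adjusted p = 3.66e-19, adjusted p = 0.0865 with an estimated correlation), as were mesothelial markers (camera adjusted p = 2.04e-08, adjusted p = 0.186 with an estimated correlation), with Muc16 called of 10 and 5 lower over the list alone. Muc16 was at 543, 26.3 and 37.3 CPM in Diaphragm replicates 1 to 3, and its call was lost without replicate 1.

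In all, 25 genes were higher and 26 lower in meninges than in diaphragm among 14831 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Meningeal and diaphragm libraries did not overlap for any of these genes, which holds for 17.1% of all genes tested and for 10% by chance. The genes were called on these same libraries, so their lack of overlap was largely set by that choice and is no separate support. The counts higher and lower were 8 and 15 without Meninges replicate 2, 7 and 12 without Meninges replicate 3 and 10 and 16 without Diaphragm replicate 3. They were 13 and 20 without Diaphragm replicate 1, 12 and 20 without Diaphragm replicate 2, 43 and 30 without Meninges replicate 1 and 67 and 38 without Skin replicate 1. With Meninges replicate 1 as the only meningeal library, a choice made after seeing the data, 3 genes were higher and 8 lower. Other settings called more genes, with 72 and 36 for the 2 tissues alone, 113 and 87 with limma voom, 178 and 120 without a filter and 628 and 304 with the DESeq2 Wald test. Of 33 called genes followed one by one, 12 were called in each of the 9 fits that left out 1 library, among them Ttr, Sfrp4, Mmp13, Emb, Chodl, Pkhd1l1, Tnxb, Wipf3 and Gucy1b3. Fgfr2, Ndnf, Ednra, Glis3, Ttn and Alpl were called in 4 of the 9, and Drp2, Gucy1a3, Sema3a and Plvap in 3. Clca3a1 has close paralogs, and how reads matching several copies were counted is not given in the sources used here, so its level is uncertain, as are those of Serpina3n and Ifi203.

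**Figure D2:**
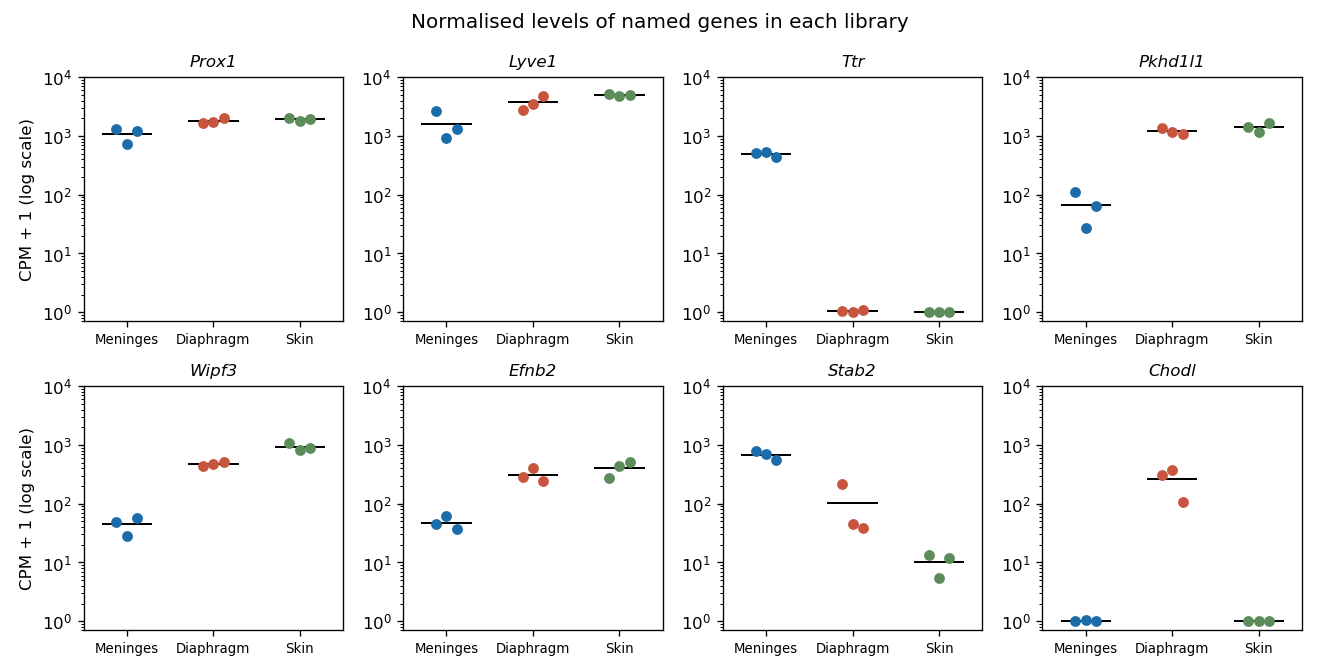
Normalised level of 8 genes in each library, as CPM + 1 on a log axis, with 1 point per library and a line at the mean of the 3 libraries of a tissue. Ttr is at 429 CPM or more in each meningeal library, and Pkhd1l1, Wipf3 and Efnb2 are lower in each meningeal library than in every diaphragm and skin library.

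Compared with skin, meningeal LECs carried more Stab2, a scavenger receptor for hyaluronan, at 683 ± 119 CPM against 9.25 ± 4.12 (log2 fold change 6.21, standard error 0.75, edgeR adjusted p = 0.00186). The growth factor Igf2 (834 ± 337 against 58.1 ± 15 CPM), the water channel Aqp1 (822 ± 328 against 68.1 ± 36.2), the mannose receptor Mrc1 (465 ± 64 against 136 ± 45) and the VEGF and semaphorin co-receptor Nrp1 (160 ± 24 against 1.73 ± 1.54) were also higher in meninges. Lower in meninges were Wipf3 (44.3 ± 15.2 against 929 ± 148 CPM, edgeR adjusted p = 1.05e-04), Pkhd1l1 (67.0 ± 43.1 against 1412 ± 245), the serine protease inhibitor Serpina3n (6.06 ± 3.53 against 249 ± 70), the hydrogen peroxide-producing oxidase Duox2 (16.1 ± 13.4 against 437 ± 145) and the kinase Bmx (4.65 ± 5.0 against 110 ± 16).

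Several genes at more than 75 CPM in meninges had no count in skin. They include Esm1, a product of endothelial tip cells (81.0 ± 14.7 CPM), the interferon-induced gene Oasl2 (79.3 ± 3.9), Dio2, which activates thyroid hormone (138 ± 112), the collagen-binding integrin Itga11 (137 ± 117) and the WNT inhibitor Nkd2 (91.4 ± 114). Ttr also had no count in skin and was at least 13.52 higher in meninges on the log2 scale against the same floor. Prrt4 (0.217 ± 0.354 against 96.8 ± 51.1 CPM) and the transcription factor Casz1 (2.37 ± 1.25 against 104 ± 58) were lower in meninges.

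Of the 25 LEC identity genes, 4 were lower in meninges than in skin and 1, Stab2, was higher, against 8 and 3 when adjusted over the list alone. The lower ones included Fgl2, the tetraspanin Cd9 (49.8 ± 8.1 against 249 ± 24 CPM) and Lyve1. The list was lower (camera adjusted p = 1.12e-05, adjusted p = 0.355 with an estimated correlation). Of 19 blood endothelial genes, 4 were higher and 1, Bmx, lower, against 9 and 1 when adjusted over the list alone. The higher ones included Aqp1, Esm1 and Plvap, a component of endothelial fenestrae (215 ± 98 against 10.8 ± 5.3 CPM). This list was higher in meninges (camera adjusted p = 1.83e-05, adjusted p = 0.236 with an estimated correlation). Interferon response genes were higher as a list of 25 (camera adjusted p = 1.97e-08, adjusted p = 0.0423 with an estimated correlation), with 2 members called, Oasl2 and Ifi44 (83.4 ± 35.1 against 3.98 ± 2.43 CPM), and 3 over the list alone. The Oasl2 call held in all 9 fits that left out 1 library, and the Ifi44 call in 2 of 9, those without Diaphragm replicate 1 or 2. Antigen presentation genes were higher (camera adjusted p = 2.99e-04, adjusted p = 0.186 with an estimated correlation), with B2m called (1057 ± 370 against 299 ± 60 CPM) and 2 of 19 passing over the list alone.

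Immediate early and dissociation-induced genes were lower in meninges than in skin (camera adjusted p = 6.65e-11, adjusted p = 0.167 with an estimated correlation), with 7 of 26 called and 9 over the list alone, among them Fosb (11.1 ± 7.9 against 365 ± 190 CPM), Fos (9.55 ± 7.11 against 194 ± 87), Zfp36 (49.4 ± 13.0 against 424 ± 248) and Jun (45.0 ± 6.3 against 324 ± 115). Meningeal fibroblast markers were higher (camera adjusted p = 8.94e-12, adjusted p = 0.0423 with an estimated correlation), with 4 of 11 called and 8 over the list alone. They were Slc47a1 and the transcription factor genes Alx4, Zic4 and Foxd1, all without a count in skin. Fibroblast markers (camera adjusted p = 1.49e-08, adjusted p = 0.28 with an estimated correlation) and mural cell markers (camera adjusted p = 3e-08, adjusted p = 0.0423 with an estimated correlation) were higher too. Thbs2 (302 ± 184 against 1.09 ± 1.44 CPM) and Col3a1 (727 ± 532 against 91.2 ± 49.9) were the 2 called of 21 fibroblast markers, against 9 higher and 1 lower over the list alone. Notch3 (40.8 ± 23.8 against 0.286 ± 0.456 CPM) was the 1 called of 13 mural markers, against 8 over the list alone. Summed fibroblast marker levels in skin ran from 855.8 to 2251 CPM, against the 2321 to 11450 CPM of the meningeal libraries.

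In all, 111 genes were higher and 85 lower in meninges than in skin by the edgeR test. The counts higher and lower were 46 and 49 without Meninges replicate 2, 38 and 36 without Meninges replicate 3, 70 and 54 without Skin replicate 1 and 74 and 55 without Skin replicate 3. With Meninges replicate 1 as the only meningeal library they were 33 and 25, and with each library's fibroblast marker level as a covariate, also chosen after seeing the data, 10 and 14. The covariate, a mean log2 CPM, itself differed between these tissues, with 5.21, 7.46 and 6.92 in Meninges replicates 1 to 3 and 0.83, 5.62 and 3.04 in Skin replicates 1 to 3. It can thus absorb any difference between meninges and skin. The drop with the covariate does not show that fibroblast-type cells gave the lost calls. Other settings called more genes, with 254 and 160 with limma voom, 401 and 209 without a filter and 1020 and 438 with the DESeq2 Wald test. Of 62 called genes followed one by one, 28 were called in each of the 9 fits that left out 1 library, among them Ttr, Wipf3, Pkhd1l1, Tnxb, Oasl2 and Fosb. Nkd2, Col3a1, Zic4 and Foxd1 were called in 4 of the 9 and Ifi44 in 2.

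Against both peripheral tissues at once, 17 genes were higher and 20 lower in meninges. The higher set included, in no order, Mmp13, Slc47a1, Ndnf, Ttr, Sfrp4, the non-coding RNA Snhg11 (47.8 ± 17.4 CPM in meninges), Shisa3 (476 ± 234) and the endothelin receptor gene Ednra (112 ± 82). The lower set included Clca3a1, Ackr3, Pkhd1l1, Gucy1b3, Tnxb, Wipf3, the transcription factor gene Glis3 (11.4 ± 5.3 CPM in meninges, 92.5 ± 33.9 in diaphragm, 176 ± 49 in skin) and Gucy1a3. Efnb2, Sema3a, Dtx1, Jun and Fgl2 were also among the 20. The meningeal libraries that raised the fibroblast sums, replicates 2 and 3, also carried more of most of the 17 higher genes, with a median log2 ratio to replicate 1 of 1.18, and Ttr was at 510, 529 and 429 CPM in replicates 1 to 3. In 20 simulations that redrew all 9 libraries with no gene changed and genes independent, the highest overlap was 0 genes higher and 1 lower. With nothing changed only false calls can overlap, so a value near 0 was set in advance. It does not show how much of the overlap the shared meningeal libraries produce. Independent lists of these sizes share 0.19 and 0.15 genes.

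Across all genes tested, the 2 sets of log2 fold changes correlated at 0.453, against a mean of 0.497 in the simulations, and their covariance was 3.734 against 1.804, a difference of 1.93. Genes are not independent replicates, and with 3 meningeal libraries a split into groups of 2 was not possible, so part of the overlap may come from the shared libraries. The counts higher and lower than both were 4 and 9 without Meninges replicate 3, 5 and 12 without Meninges replicate 2 and 6 and 12 without Diaphragm replicate 3. They were 8 and 15 without Diaphragm replicate 2, 11 and 17 without Diaphragm replicate 1 and 29 and 27 without Meninges replicate 1, and 1 and 6 with Meninges replicate 1 as the only meningeal library. With the fibroblast marker level as a covariate they were 5 and 11, which included 3 of the 17 and 10 of the 20. This level differed between meninges and skin, so the covariate can absorb other differences between them.

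**Figure D3:**
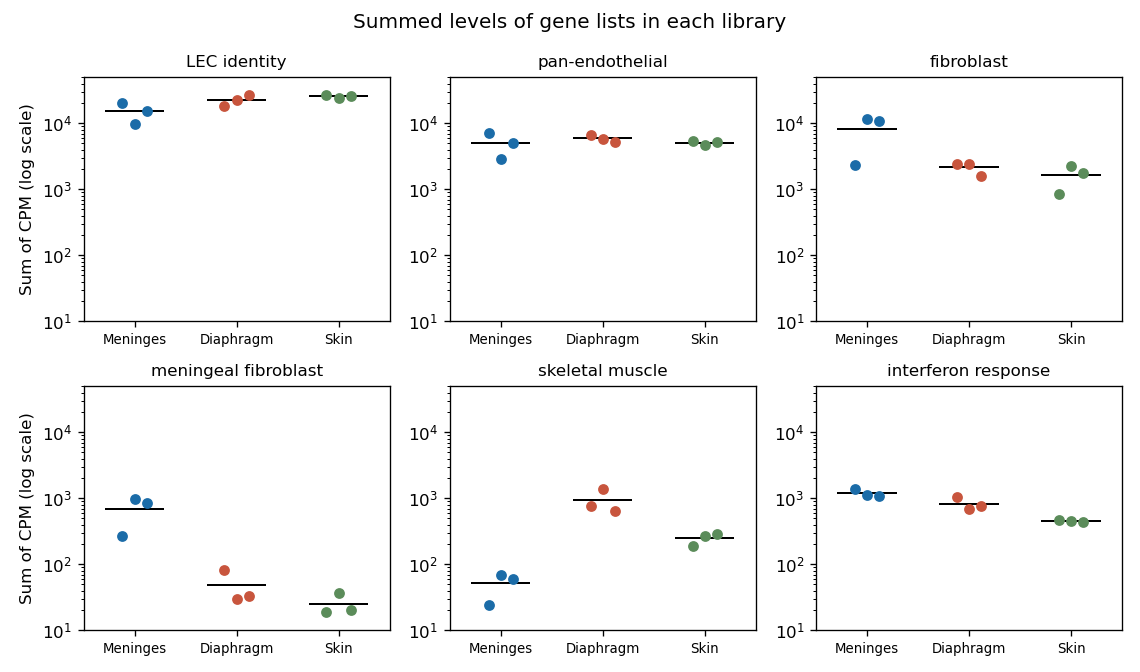
Summed CPM of the tested members of 6 gene lists in each library, on a log axis, with 1 point per library and a line at the mean of the 3 libraries of a tissue. Fibroblast markers sum to 11450 and 10710 CPM in Meninges replicates 2 and 3 and to 2321 CPM in replicate 1, and skeletal muscle markers are highest in diaphragm.

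Diaphragm and skin LECs differed in 6 called genes, and all 6 are named here. Chodl, which encodes a membrane lectin, was at 261 ± 137 CPM in diaphragm and had no count in skin, at least 12.61 higher on the log2 scale against the floor (edgeR adjusted p = 7.63e-04). Sytl2, a regulator of vesicle traffic (65.4 ± 32.2 CPM), and Oasl2 (34.7 ± 29.9) also had no count in skin. The junction gene Jam2 (118 ± 93 against 0.222 ± 0.257 CPM) and Ifi203 (39.0 ± 18.1 against 0.205 ± 0.074) were higher in diaphragm. Emb was lower, at 0.0123 ± 0.0213 CPM in diaphragm and 34.1 ± 36.0 in skin. The Chodl and Oasl2 calls held in all 9 fits that left out 1 library. The Emb call was lost without any 1 diaphragm library, Ifi203 without Diaphragm replicate 1 or Skin replicate 1 or 3, Sytl2 without Diaphragm replicate 1 or 2 and Jam2 without Diaphragm replicate 1.

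As lists, interferon response genes (camera adjusted p = 1.12e-05, adjusted p = 0.0423 with an estimated correlation) and blood endothelial genes (camera adjusted p = 4.51e-06, adjusted p = 0.208 with an estimated correlation) were higher in diaphragm than in skin. Oasl2 was the 1 called interferon gene of 25, against 3 over the list alone, and no blood endothelial gene of 19 was called, against 5. Skeletal muscle markers (camera adjusted p = 2.29e-11, adjusted p = 0.11 with an estimated correlation), summing to 633.8 to 1391 CPM in diaphragm and 190.9 to 287.3 in skin, and mesothelial markers (camera adjusted p = 1.74e-08, adjusted p = 0.186 with an estimated correlation) were higher in diaphragm too. Mesothelial markers summed to 1630 CPM in Diaphragm replicate 1 but to 355.5 and 356.4 in replicates 2 and 3, within the 187.3 to 510.2 CPM of skin, and the limma camera adjusted p was 9.71e-05 without Diaphragm replicate 1. No member of either was called, against 5 of 18 and 8 of 10 over the list alone. Fibroblast markers (limma camera adjusted p = 5.94e-04, adjusted p = 0.529 with an estimated correlation) and mural markers (limma camera adjusted p = 0.00181, adjusted p = 0.158 with an estimated correlation) were also higher in diaphragm. None was called, against 1 of 21 and 5 of 13 over the list alone, and the fibroblast list did not pass without Skin replicate 1 (limma camera adjusted p = 0.381). Keratinocyte markers were lower in diaphragm (limma camera adjusted p = 0.0394, adjusted p = 0.301 with an estimated correlation), with none of 5 called and 3 over the list alone. They summed to 40.33 to 131.5 CPM in diaphragm and 176.8 to 474.3 in skin. The edgeR counts of 5 higher and 1 lower became 54 and 4 without Skin replicate 2, 26 and 4 without Meninges replicate 1, and 10 and 3 without Skin replicate 1. They were 9 and 0 without Diaphragm replicate 3, 8 and 2 without Skin replicate 3 and 2 and 0 without Diaphragm replicate 1. With all 9 libraries, 1749 genes had an unadjusted p under 0.05, and the DESeq2 Wald test called 641 higher and 423 lower. Fitted with the 2 tissues alone, edgeR called 1 higher and 0 lower. With Meninges replicate 1 as the only meningeal library they were 60 and 22.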

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

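Tests with Meninges replicate 1 alone and with the fibroblast marker level as a covariate were chosen after the result was seen. No named gene that was called changed direction under any setting. Among gene lists called in the comparisons, 5 changed direction and none passed when it did. With Meninges replicate 1 alone, these were pan-endothelial (camera adjusted p = 0.829), fibroblast (0.666) and erythroid and platelet genes (0.444) in meninges against diaphragm. With the covariate, they were fibroblast genes in meninges against skin (0.856) and diaphragm against skin (0.788), which follows from its construction. Except where a reason is stated, the cause was not tested.

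Counts are given as higher and lower for meninges against diaphragm, meninges against skin, diaphragm against skin and meninges against both, and were 25 and 26, 111 and 85, 5 and 1, and 17 and 20. DESeq2 size factors, upper-quartile factors and removal of genes of other cell types, with ribosomal protein and mitochondrially encoded genes, kept each count within 1.5 times. The DESeq2 Wald test gave 628 and 304, 1020 and 438, 641 and 423, and 265 and 149. It included all 17 and all 20 genes that differed from both tissues, and called 191, 167 and 149 unchanged genes in simulated data. Without a filter the counts were 178 and 120, 401 and 209, 215 and 90, and 114 and 77. limma voom gave 113 and 87, 254 and 160, 0 and 1, and 86 and 36, which included 10 of the 17 genes higher than both and 19 of the 20 lower. It called 5, 5 and 1 unchanged genes in simulated data. The stricter filter gave 11 and 2 for diaphragm against skin, and the robust fit 32 and 4 there, with 31 genes lower than both. With 2 tissues alone, 72 genes were higher in meninges than diaphragm, 100 and 58 differed between meninges and skin, 1 and 0 between diaphragm and skin, and 28 were higher than both. glmTreat, which asks for a larger difference, gave 17 and 15, 61 and 32, 5 and 1, and 10 and 11.

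With Meninges replicate 1 alone the counts were 3 and 8, 33 and 25, 60 and 22, and 1 and 6. This fit has fewer libraries, and the lone one is assumed to vary like the others. With the covariate they were 24 and 28, 10 and 14, 1 and 1, and 5 and 11. The covariate differed between meninges and skin, so lost calls there cannot be assigned to fibroblast-type cells. Leaving out each library in turn gave 7 to 67 and 12 to 38, 38 to 157 and 36 to 97, 2 to 54 and 0 to 4, and 4 to 29 and 9 to 27, with 32 to 42 list calls. List calls numbered 42, with 6 under an estimated correlation and 26 with fry. With the replicate number as a replicate block, the counts were 37 and 33, 139 and 92, 14 and 2, and 24 and 23, with 37 list calls. Deviations of libraries from their tissue means correlated between -0.021 and 0.051 for equal replicate numbers and between -0.057 and 0.039 for unequal ones. These values gave no sign of pairing, but cannot show that the number marks no shared animal or day. At this spread, simulated 2-fold changes were not detectable.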

Other observations

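The tests of fibroblast-type cells and of a lower LEC share were chosen after the result was seen. Other gene lists also differed between the tissues. HOX genes, which mark position along the body axis, were lower in meninges than in diaphragm as a list (limma camera adjusted p = 1.12e-05, adjusted p = 0.0472 with an estimated correlation). No single member of the 16 tested was called, over all genes or over the list alone, and the median log2 fold change was -1.6. Against skin the HOX list did not pass in meninges (limma camera adjusted p = 0.0654). Schwann cell markers were higher in meninges than in diaphragm (limma camera adjusted p = 8.14e-04, adjusted p = 0.186 with an estimated correlation), with none of 10 called and 2 passing over the list alone. They were also higher than in skin by the list test (limma camera adjusted p = 0.00819, adjusted p = 0.208 with an estimated correlation), with none called. Of the 10, 9 had a fitted fold change above 0, but the summed level went the other way, with 467 CPM in meninges and 646.7 in skin. Bone and cartilage markers were higher in meninges than in skin as well (limma camera adjusted p = 1.87e-05, adjusted p = 0.208 with an estimated correlation), with 2 of 6 called. Brain barrier endothelial genes were higher in meninges than in diaphragm (limma camera adjusted p = 0.00556, adjusted p = 0.208 with an estimated correlation), with none of 14 called, over all genes or over the list alone.

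Among 32 axon guidance genes, 2 were higher and 3 lower in meninges than in skin, against 9 and 7 over the list alone, and the list did not pass (limma camera adjusted p = 0.4). Nrp1 and its partner receptor Plxnd1 (199 ± 35 against 27.1 ± 11.6 CPM) were the higher ones. Sema3a, Sema6a (535 ± 50 against 1433 ± 386 CPM) and Efnb2 were the lower ones. Ribosomal protein genes were lower in meninges than in diaphragm (limma camera adjusted p = 1.12e-04, adjusted p = 0.355 with an estimated correlation), with none of 78 called. Lists of glycolysis, oxidative phosphorylation, proliferation and basement membrane genes passed in none of the 3 comparisons, with lowest limma camera adjusted p of 0.635, 0.587, 0.622 and 0.742.

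A candidate explanation for the 17 genes higher in meninges than in both other tissues is fibroblast-type cells in the meningeal sort, whose markers were higher in Meninges replicates 2 and 3. The median log2 ratio of these replicates to replicate 1 was 1.18 over the 17 genes, 2.19 over the fibroblast list (lower quartile 1.71) and 0.15 over all genes tested. It was 0.97 over the meningeal fibroblast list (lower quartile 0.29), -1.03 over the pan-endothelial list and -0.51 over the LEC identity list. Meningeal fibroblast markers also summed to 272.1 CPM in replicate 1, against 18.89 to 82.55 CPM in the diaphragm and skin libraries. All 21 fibroblast markers reached 10 CPM in some diaphragm or skin library, and Col1a1, among the most abundant, was at 543, 2917 and 2847 CPM in Meninges replicates 1 to 3. Of the 17 genes, 6 were at or above the lower quartile of the fibroblast list and 4 at or under 0 (Plvap, Itih5, Ctsd and Ttr). Fibroblast-type cells, which the CD31 gate should remove, and a tissue difference cannot be told apart for the set.

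The 20 genes lower in meninges than in both were weighed against the share of LECs. A lower share of LECs in the meningeal sort could lower LEC transcripts in general. The 20 genes had a median log2 fold change of -2.9 against diaphragm and -3.48 against skin, while the LEC identity list had medians of -0.54 and -0.53 and lower quartiles of -1.06 and -1.63. The 20 genes were taken for being called lower, and no gene called against diaphragm had an absolute log2 fold change under 1.89. Their fall past the list's lower quartile against diaphragm was thus set by that choice. That comparison alone therefore cannot tell a lower LEC share from a difference between the tissues. A lower share alone would lower these genes about as much as other LEC genes. With glmTreat, which tests for a difference beyond a log2 fold change of 1, 11 of the 20 were called lower in both comparisons. That is past the medians of the LEC identity list. These values argue against a lower LEC share as the only source for those 11. For the rest the question stays open.

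Other splits of the libraries were set against these counts. A draw took 100 splits of the 9 libraries into groups of 3, the real one included. Only the real one (1 split) reached 17 genes higher than both or 20 lower than both, a share under 0.05. The highest other drawn gave 1 for either count. Since the labels do not say whether libraries came from separate animals or pools, this rank does not exclude chance. The draw held no other split that set the 3 meningeal libraries as 1 group against both others. In the 9 splits that did so and mixed diaphragm with skin, 7 to 11 genes were higher and 12 to 16 lower. For the pairs of tissues, 10 splits are too few for a share under 0.05. The real split was the 1 split that reached 51 called genes for meninges against diaphragm (highest other 0), 196 for meninges against skin (0) and 6 for diaphragm against skin (1).

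Ttr stood at 510, 529 and 429 CPM in Meninges replicates 1 to 3. It is an abundant transcript of the choroid plexus, the secretory epithelium of the brain ventricles, which the CD31 gate should remove. Of 14 other choroid plexus markers, 7 were above each diaphragm and skin library in all 3 meningeal libraries, against 4.59% of all genes tested. The markers, unlike the genes tested, were not filtered for low counts, so these shares rest on unlike sets. Of the 14, 8 reached 10 CPM in any library, 3 of them in a diaphragm or skin library. These markers were not among the gene lists fixed before the data were examined. The bound, set before this test, was more than 7 of 14. RNA of choroid plexus cells may thus be a source of Ttr but cannot be told apart from expression in meningeal LECs. Levels of the markers included 18.8, 10.7 and 51 CPM for Kl and 5.38, 13.2 and 0.582 CPM for Kcne2 in Meninges replicates 1 to 3.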
